A study of Bos taurus with 8 samples.

How the data were processed

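The series holds 8 single-colour Cy3 arrays of bovine whole blood RNA, 4 from blood kept with cowpea leaf phenolic extract (CPE) and 4 from untreated blood (CONTROL). Per the labels, fresh blood of 5 female Holstein Friesian cows was incubated for 30 min at 37 °C under 5% CO2, with 10 µg/ml extract in the treated group. The cows had been given a probiotic for 60 days before the blood was drawn. RNA integrity numbers were above 7 per the labels. The series text says that pooled RNA of each group was hybridised. Which cows entered which pool or array is not given in the sources used here.

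The deposited scanner files hold signal intensity per spot, made by the authors with Agilent Feature Extraction 10.10.1.1. The processed signal intensity in these deposited files had been background-subtracted and spatially detrended by that software, with low values set to a floor, and had not been normalised between arrays. The deposited series table holds log2 values, averaged per group by the authors. Set against the scanner files, these log2 values were those of a shift to each array's 75th percentile, with each probe centred on its median over the 8 arrays. The authors' test for changed genes is not given in the sources used here.

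Each array holds 45220 spots, of which 1417 were control spots and were left out, apart from the spike-in probes. Spots that the scanner software marked as outliers, 12 to 73 per array, were left out of the probe averages, so some genes have no value on an array. Log2 processed signal was used minus the 75th percentile of each array, and duplicate spots of a probe were averaged. The 43653 probes were named in order of preference: 26695 through their transcript accession in the reference annotation, 6724 through a file symbol found there, and 1456 through a file symbol alone. The remaining 8778 had no gene name and entered probe counts only. Positions are not given, because the array design refers to another genome build than the reference annotation, which served for names only.

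A probe was tested when the scanner software called it well above background on all arrays of at least 1 group. A gene was represented by its probe with the highest mean over the 8 arrays. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are log2 differences, CPE minus CONTROL, with the standard error (SE) of the model and n = 4 arrays per group unless stated. A gene needed values on at least 2 arrays of each group. The 30 gene lists were fixed before the data were examined, as were the tests over the whole array and the rules for naming genes. Lists of at least 5 measured genes were tested with limma's camera (inter-gene correlation 0.01), adjusted over the lists, with an estimated correlation and with fry as alternatives. These tests used genes with a value on all 8 arrays, which left out 1 counted gene in 7 lists of the lit area and 1 or 2 in 8 lists over the whole array. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move to the same side.

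Named genes are the 10 largest rises and the 10 largest falls among named genes past the threshold, well above background on all 8 arrays and with groups that did not overlap. A further rule took the 3 largest lower bounds each way among genes of which no probe was well above background on any array of 1 group. For that bound, each array of the dim group is set to its lowest well-above-background value or to its own value, whichever is higher. Over the whole array the own value was always the higher for the named genes, so bounds are printed for the lit area only. Another rule took up to 2 rises and 2 falls per gene list. Numbered locus names were not eligible.

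After the data had been seen, an area of the array was defined without use of the groups, called the lit area. For each spot, the 90th percentile of log2 raw median intensity over its 61 nearest spots was taken as a local value. A spot was lit on an array when its local value exceeded that array's 90th percentile of local values minus 1.5 log2 units. The lit-area comparison used spots lit on all 8 arrays, with scaling, naming and tests as over the whole array. This comparison and its alternatives were chosen after seeing the data. Those alternatives were 121 neighbours, a limit of 1 or 2 log2 units, and local centring, which subtracts from each array its local median deviation over the 61 nearest lit spots.

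Alternatives fixed beforehand were quantile normalisation, scaling to the median of bright probes, no scaling, scaling to spike-in RNA, and normexp background correction (offset 50). Others were no filter or a stricter filter on dim probes, trended and robust variance, array weights, the replicate number as a block, and the mean over a gene's probes. A minimum change (treat, log2 0.5), an adjusted p under 0.01 and leaving out each array were also fixed. Normexp had been planned on mean spot intensity, which the files used here do not hold, so median spot intensity was used. The 10 spike-in probes were compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15 served for the array maps and the remaining tests.

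The fit was tested on simulated data with the observed spread between arrays, independent noise in each gene and 100 genes changed at each size. In the lit area, 84% of genes changed by 1 log2 unit and 100% of those changed by 2 were recovered, and 3.16% of calls were false. On the whole array the same shares were 1% and 23%, with 11.1% of calls false. The real comparisons called many more genes, on arrays with uneven signal, so these shares are not the power or error rate of the real fits. The number of arrays limits the precision of every value.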

Results

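Transcript levels were measured by array in bovine whole blood that had been kept for 30 min with a phenolic extract of cowpea leaf (CPE) or without it (CONTROL). The comparison asks which transcripts of blood cells differ after contact with the extract. Each group had 4 arrays. RNA was pooled within each group per the series text, so the 4 arrays of a group may be technical replicates, and every SE and p describes the spread between arrays, not between cows. Each group lay on its own slide, and the 2 slides were scanned about 7 months apart. The version of the array grid used to read the spots also differed between the 2 slides. Batch and group cannot be told apart in any comparison of these arrays, and no fit with slide as a term could be had.

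The 75th percentile of processed signal was 205.9 ± 60.0 intensity units in CPE (SD, n = 4; range 135 to 280) and 110.7 ± 41.0 in CONTROL (SD, n = 4; range 53.4 to 150). The share of spots well above background was 45.5% ± 5.73 in CPE and 32.9% ± 4.70 in CONTROL (SD, n = 4 each). In both groups, large connected parts of each array were much dimmer than the rest, with 11.7% to 35.6% of spots well above background against 57.5% to 69.3% in the lit part. Spots in the lit part of an array made up 43.15% to 50.2% of the CPE arrays and 31.9% to 40.8% of the CONTROL arrays. Raw brightness at the 90th percentile was 2112 to 2579 intensity units in the lit part of the 8 arrays and 146 to 385 outside it. The dark parts differed in shape between arrays, and 13028 spots, 29.7% of those on the array, were lit on all 8. All these shares of spots leave out the control spots. No spot was saturated.

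**Figure D1:**
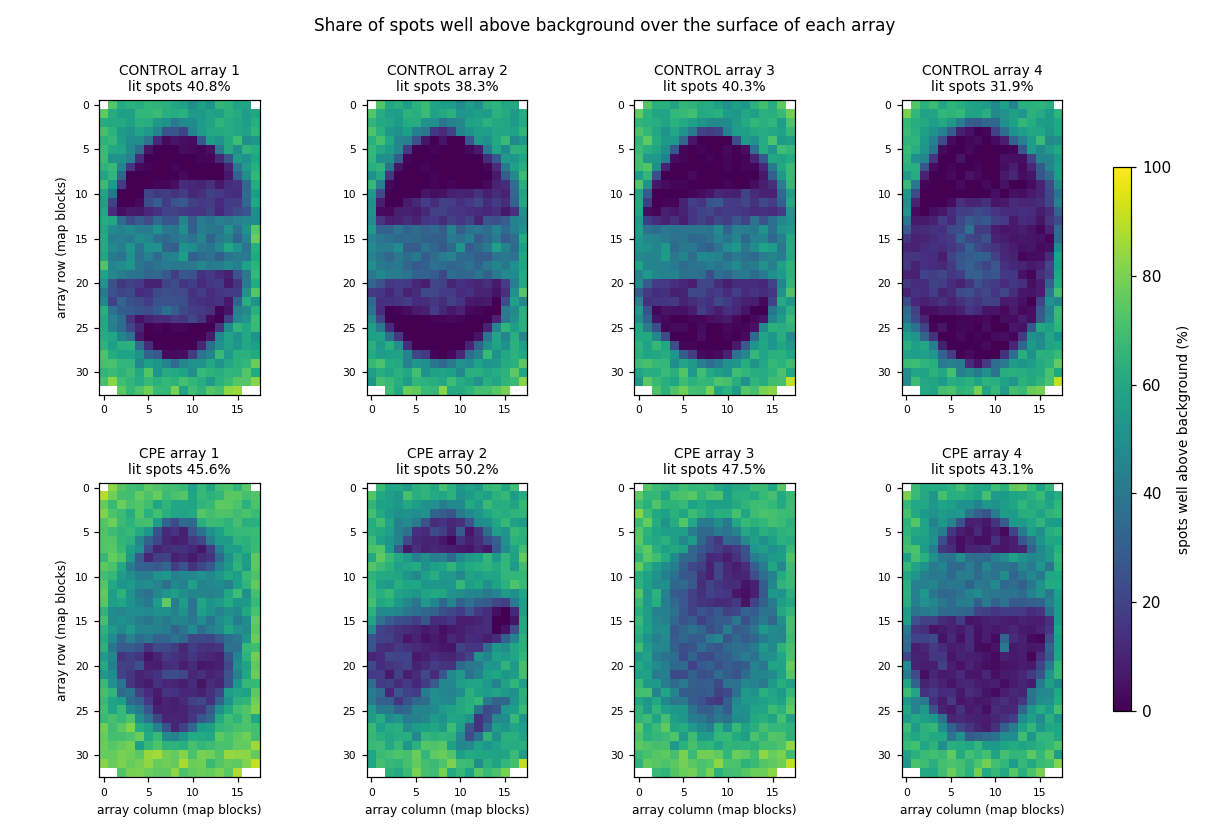
Maps of the 8 arrays, CONTROL above and CPE below, with array column and row in map blocks and colour giving the percentage of spots well above background in each block. The dark patches are the dimmer parts of the surface, and each title gives the percentage of lit spots, from 31.9% on CONTROL array 4 to 50.2% on CPE array 2.

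Over the whole array, the comparison fixed before the data were examined, transcripts of RPLP2, a protein of the ribosomal stalk, and of ACTB, the cytoplasmic actin, read higher in CPE. FOS, a transcription factor induced within minutes of cell stimulation, and NEFH, a neurofilament subunit, read lower. RPLP2 (NM_174788) was 102-fold higher (log2 6.67, SE 0.94, limma adjusted p = 0.000116) and ACTB (NM_173979) was 37.6-fold higher (log2 5.23, SE 0.47, adjusted p = 1.67e-06). FOS (NM_182786) fell by 3.75 on the log2 scale (SE 0.49, adjusted p = 5.44e-05) and NEFH fell by 4.15 (SE 0.56, adjusted p = 7.89e-05). In each named gene, all CPE arrays lay on the same side of all CONTROL arrays with a value, which were 3 for SPEG and 4 for the others. Of 8349 genes tested, 1106 were higher and 1773 lower, and 4262 had an unadjusted p under 0.05. The groups did not overlap in 3615 genes. Chance gives 2.86% of genes chosen without the groups, but the filter on dim probes used them, so that share is only a rough guide. With the stricter filter, which kept probes well above background on all 8 arrays, 129 of 6102 genes were higher and 2226 lower.

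Further rises over the whole array had log2 changes of 5.78 for POLR2K, a subunit of RNA polymerases, 5.73 for STRN3, 5.00 for SSPO, 4.56 for CHRD, 4.40 for HMGN2, and 4.02 for METTL2A (METTL2B in the files) and CYTH2. None of the spots behind these rises, RPLP2 and ACTB included, was lit on any CONTROL array. The signal of STRN3, CHRD and METTL2A came from spots lit on 0 of the 4 CPE arrays as well. POLR2K had a second probe in the lit area, with a log2 change of 0.34, and SSPO had one at −0.078. The other named falls had log2 changes of −4.43 for the tubulin gene TUBA1D, −4.18 for SSLP1, −3.94 for SCARA3, −3.88 for ASB2, −3.81 for NLGN3, −3.76 for FAM209A (FAM209B in the files), −3.73 for SPEG and −3.39 for WWOX. Of the 10 named falls, 7 came from spots lit on all 8 arrays, the others being TUBA1D, NLGN3 and WWOX. WWOX was 0.65 higher at a lit probe. Other probes well above background on all 8 arrays read 2.02 over the whole array for RPLP2, −0.78 for POLR2K, −1.65 and −1.20 for SSPO, −0.91 for METTL2A, −1.75 for WWOX and −0.072 for SPEG. The values of −0.78 for POLR2K and −1.20 for SSPO belong to the lit probes given above, scaled here over the whole array. SSLP1 had no fall when its probes were averaged (0.90), the rise of SSPO was then 0.24 and not past the threshold, and that of HMGN2 was 2.94 and not past it with normexp. RPLP2 and POLR2K read lower on CPE array 2 than on the other CPE arrays.

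Some genes were well above background on all 4 arrays of 1 group and at no probe on any array of the other. No fold is given for them over the whole array, because the dim group lay at or above the lowest well-above-background value and no lower bound follows from it. The strongest toward CPE were the thymosin gene TMSB4X (log2 level 8.63 ± 0.35, SD, n = 4), TLNRD1 (MESDC1 in the files) and PALM. Their spots were lit on 0 of the CONTROL arrays, and those of TLNRD1 and PALM on 0 of the CPE arrays as well. The strongest toward CONTROL were PRRG1, from a spot lit on all 8 arrays, and CNDP1 and MRAP, from spots lit on none. In all, 603 such genes read higher in CPE, 509 of them past the threshold, and 41 read lower, all 41 past it.

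The position of a spot went with the direction of its call. Of 4881 genes whose spot was lit on all 8 arrays, 10 were called higher and 1322 lower. Of 788 genes whose spot was lit on the 4 CPE arrays but dark on some CONTROL array, 274 were called higher and 32 lower. Of 265 genes whose spot was dark on some CPE array but lit on the 4 CONTROL arrays, 0 were called higher and 73 lower. Their median log2 change of −1.13 was near the −1.07 of genes lit on all 8 arrays. Of 2415 genes with a spot dark on some arrays of both groups, 822 were called higher and 346 lower. The scaling also moved the split, since the median log2 change of all genes was −0.85. Scaling to bright probes moved that median by 0.89 and gave 1897 genes higher and 1284 lower, and no scaling moved it by 0.94 and gave 1489 and 565. Spike-in scaling moved it by −0.76 and called 5689 genes, and normexp moved it by 0.47 and called 1577. Array weights, whose estimation stopped before it converged, called 6817 genes. Without CPE array 2 the whole-array count of 2879 genes dropped to 1833, and it was 1765 without CONTROL array 2, 1898 without CONTROL array 3 and 1888 without CONTROL array 4.

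No gene list passed the test over the whole array (camera, 0 of 30 lists, lowest adjusted p = 0.289). Unadjusted, 3 lists had a p under 0.05 by camera and 7 by fry, and none passed by fry or with an estimated correlation after adjustment. Markers of B cells had 5 genes higher and 0 lower of 16, red cell markers 5 and 2 of 18, and complement and coagulation genes 0 and 10 of 20. Immediate-early genes had 2 higher and 9 lower of 22. The median and the camera direction differed in sign in 18 of the 30 lists. Adjusted over the list alone, the counts were the same in 13 lists and differed by at most 4 genes in the other 17.

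In the lit area, a comparison chosen after seeing the data, transcripts of FOS read lower in CPE, and those of the T cell kinase gene TXK and the ribosomal protein gene RPS21 read higher. FOS (NM_182786) was 6.19-fold lower in CPE (log2 −2.63, SE 0.08, limma adjusted p = 5.38e-07), and its level was −0.37 ± 0.11 in CPE against 2.26 ± 0.02 in CONTROL (log2 above the 75th percentile, SD, n = 4 each). TXK (NM_001206148) was 5.43-fold higher (log2 2.44, SE 0.16, adjusted p = 1.26e-05). RPS21 (NM_001040581), of the small ribosomal subunit, was 3.66-fold higher (log2 1.87, SE 0.34, adjusted p = 0.00258). Of 5348 genes tested, 1355 were higher and 1184 lower, of which 311 and 259 changed at least 2-fold, and 2934 had an unadjusted p under 0.05. The median log2 change was 0.055. The groups did not overlap in 2664 genes, where chance gives 2.86%, with the same limit from the filter on dim probes.

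Among lit genes well above background on all 8 arrays, the largest rise was that of LAMA4 (NM_001205965), a laminin chain, at 6.19-fold (log2 2.63, SE 0.40, adjusted p = 0.00105). MINDY3 (NM_001076107, FAM188A in the files), a deubiquitinase, rose by 2.46 on the log2 scale (SE 0.29). MOCS2, an enzyme of molybdenum cofactor synthesis, rose by 2.38 (SE 0.53), RNMT, the mRNA cap methyltransferase, by 2.32 (SE 0.41), and ASS1, argininosuccinate synthase, by 2.23 (SE 0.26). The potassium channel gene KCNF1 rose by 2.05 (SE 0.12), NTAN1 by 2.02 (SE 0.35) and WTAP, a subunit of the mRNA m6A methyltransferase complex, by 1.87 (SE 0.29). At least 1 array lay apart from the others of its group in MINDY3 and ASS1. A second lit probe of WTAP had a log2 change of 0.19.

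Among the same genes, the largest fall was that of SSLP1 (NM_001105478), at 8.30-fold lower (log2 −3.05, SE 0.30, adjusted p = 9.93e-05). NEFH (ENSBTAT00000029508) fell by 3.02 on the log2 scale (SE 0.17), the muscle kinase gene SPEG by 2.84 (SE 0.17, n = 3 in CONTROL), the scavenger receptor gene SCARA3 by 2.81 (SE 0.16) and ASB2 by 2.75 (SE 0.11). FAM209A had a log2 change of −2.63 (SE 0.18), RUNX1T1, a transcriptional corepressor, −2.23 (SE 0.09), ELMO1, a regulator of phagocytosis and cell movement, −2.22 (SE 0.08) and PNMA2 −2.17 (SE 0.32). The call of PNMA2 ended with normexp (−0.73), and in PNMA2, ASB2 and ELMO1 at least 1 array lay apart from the others of its group. Among genes not well above background on any array of 1 group in the lit area, the natriuretic peptide gene NPPB read at least 3.56-fold higher, SYBU at least 2.79-fold and KCNE3 at least 2.46-fold. PRRG1 read at least 24.8-fold lower, the cadherin gene CDH12 at least 5.31-fold and the matrilin gene MATN2 at least 4.51-fold.

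**Figure D2:**
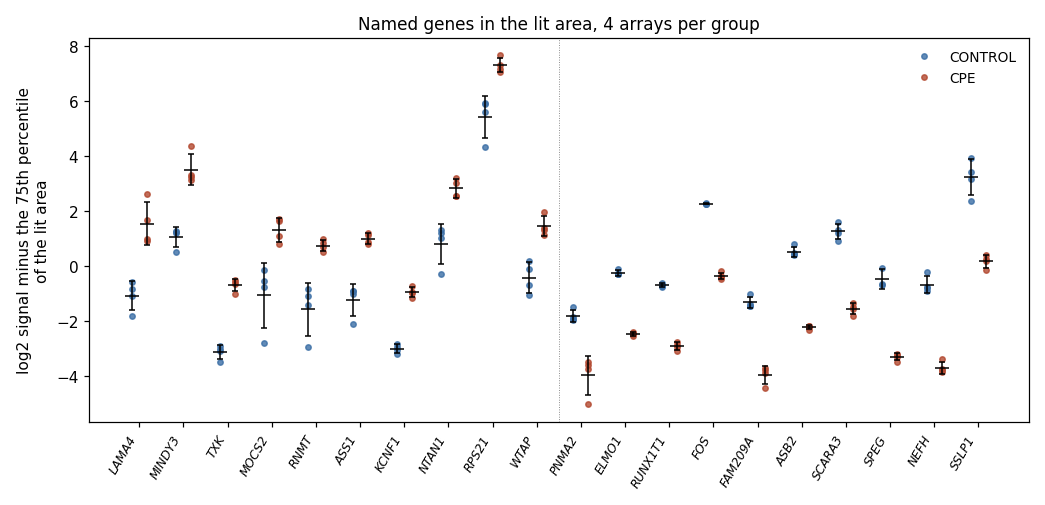
Log2 signal minus the 75th percentile of the lit area for the 20 named genes, with a point per array, the group mean and its SD (n = 4 per group, but 3 in CONTROL for SPEG), rises to the left of the dotted line and falls to its right. The groups do not overlap in any of these genes, and FOS lies at 2.26 in CONTROL and −0.37 in CPE.

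The lit-area count was lower without scaling between arrays, at 296 genes higher and 605 lower after a shift of −0.18 in the median of all genes, and with normexp, at 1166 genes. It was higher after local centring, at 3852 genes. Without a filter on dim probes, 1390 of 8148 genes were higher and 2050 lower. Over the 5348 genes in both comparisons, the log2 changes correlated across genes with r = 0.68, genes not being independent replicates. The same direction was called in both for 1100 genes, 31 higher and 1069 lower, and opposite directions for 23. For 4897 of the 5348 genes both comparisons used the same probe on the same arrays. The correlation and the shared calls are therefore no independent support for either comparison. Of the genes called higher over the whole array, 1021 had no tested probe in the lit area. Between arrays of a group, r across lit probes was 0.985 to 0.997 in CONTROL and 0.970 to 0.998 in CPE, against 0.919 to 0.971 between groups. Pairs of probes for the same gene had changes that correlated with r = 0.41 in the lit area (969 pairs) and r = 0.13 over the whole array (1549 pairs). The 2 probes changed in the same direction in 64.6% of pairs in the lit area. Over the whole array, where the median change of all genes was −0.85, they did so in 83.3%.

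By camera against all other genes, the lists of ribosomal proteins, T cells and oxidative phosphorylation passed in the higher direction in the lit area, and the neutrophil list in the lower. None of the 4 passed with an estimated correlation (adjusted p = 0.291 for each). Of 51 ribosomal protein genes, 32 rose, 2 fell and 17 passed neither way (median log2 change 0.34, camera adjusted p = 0.00119 on 50 of them). RPS21 rose by 1.87 and RPS25 by 1.28 (SE 0.30), and RPS12 fell by 0.31 (SE 0.08). Adjusted over the list alone, 32 rose and 3 fell. The counts higher and lower were 18 and 7 with quantile normalisation, 3 and 1 without scaling, and 12 and 0 with normexp. The adjusted p of the list ran from 3.4e-06 to 0.278 over 23 settings and was under 0.05 in 21, the others being quantile normalisation (0.278) and normexp with quantile (0.160). On the whole array, 10 of 75 were higher and 1 lower (camera adjusted p = 0.844).

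Of 15 T cell markers in the lit area, 8 rose and none fell (median log2 change 0.48, camera adjusted p = 0.0459), and 3 rose without scaling. CD5, a surface receptor of T cells, rose by 1.36 (SE 0.21), and CD3D, a chain of the T cell receptor complex, by 1.05 (SE 0.12). The adjusted p of the list ran from 0.00754 to 0.0954 over 23 settings and was under 0.05 in 14. Of 5 markers of gamma delta T cells, a large share of cattle lymphocytes, 3 rose and none fell (camera adjusted p = 0.420). CD163L1, of the WC1 family, rose by 0.61 (SE 0.12). The whole-array comparison had 2 of 23 T cell markers higher and 1 lower (camera adjusted p = 0.870).

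Of 10 neutrophil markers in the lit area, 6 fell and 2 rose (median log2 change −0.81, camera adjusted p = 0.0459 on 9 of them). ALPL, the alkaline phosphatase of neutrophil membranes, fell by 2.22 (SE 0.15) and was well above background on 1 of the 4 CPE arrays, and the interleukin 8 receptor gene CXCR2 fell by 1.11 (SE 0.27). BPI, a bactericidal granule protein, rose by 0.44 (SE 0.09, n = 3 in CONTROL), and S100A12 by 0.25 (SE 0.09), a rise that turned to −0.077 with quantile normalisation and to −0.18 with normexp and quantile. The adjusted p of the list ran from 0.00271 to 0.160 over 23 settings and was under 0.05 in 12. The whole-array comparison had 4 of 20 higher and 6 lower (camera adjusted p = 0.844).

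Of 33 genes of oxidative phosphorylation in the lit area, 15 rose and 1 fell (median log2 change 0.22, camera adjusted p = 0.0459), against 2 and 1 without scaling and 8 and 1 with normexp. UQCRFS1 and UQCRC2, subunits of respiratory complex III, rose by 1.83 (SE 0.34) and 1.60 (SE 0.43), with 0.57 at a second lit probe of UQCRFS1, and NDUFC1, of complex I, fell by 1.70 (SE 0.22). The adjusted p of the list ran from 0.00221 to 0.171 over 23 settings and was under 0.05 in 12. The whole-array comparison had 5 of 48 higher and 2 lower (camera adjusted p = 0.870).

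Those 4 lists were the ones past camera's threshold among 28 tested in the lit area. With an estimated correlation none passed after adjustment, 4 had an unadjusted p under 0.05, and fry called 21. Without CPE array 1, CPE array 4, CONTROL array 1 or CONTROL array 3 the number of lists was 1, and without CONTROL array 2 it was 2. Of all genes named in the lit area by any rule, 41 kept their direction and lost their call with normexp and 39 without scaling, and 2 more reversed with normexp. Counts adjusted over the list alone were the same in 21 lists and differed by at most 2 genes in the other 7. The median and the camera direction differed in sign in 4 lists, those of heat shock, monocyte, NK cell and platelet genes.

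Immediate-early genes, which respond to stimulation without new protein synthesis, moved both ways in the lit area. Of 10 tested, 5 fell and 3 rose (median log2 change −0.53, camera adjusted p = 0.115). Besides FOS, the falls were DUSP1, a phosphatase of MAP kinases, at −2.01 (SE 0.09), NR4A2 at −1.79, RHOB at −1.35 and KLF6 at −0.73. The rises were IER2 at 1.11 (SE 0.18), FOSB at 0.68 (SE 0.12) and PPP1R15A at 0.40. Of 8 cytokine genes, 3 fell and none rose (camera adjusted p = 0.0965). GRO1, the neutrophil-attracting chemokine CXCL1, was 19.8-fold lower (log2 −4.31, SE 0.27), at a spot well above background on 3 of the 4 CPE arrays. CSF1, the macrophage growth factor, passed in the lower direction, but its probe was not well above background on any CPE array, so no size is given. IL1RN, the interleukin 1 receptor antagonist, had a log2 change of −1.32.

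Of 17 complement and coagulation genes in the lit area, 8 fell and 2 rose (camera adjusted p = 0.0990), and 9 and 3 did so adjusted over the list alone. C5 fell by 1.83 (SE 0.13), with 2 of the 4 CPE arrays well above background, and CFB fell by 1.22 (SE 0.16), both of the complement cascade, and the thrombin receptor gene F2R rose by 0.69 (SE 0.10). Of 13 chemokine and cytokine receptors, 6 fell and 2 rose (camera adjusted p = 0.420), and 7 and 3 did so adjusted over the list alone. CXCR1 fell by 0.99 (SE 0.19). Of 21 antioxidant and NRF2 target genes, 6 rose and 4 fell (camera adjusted p = 0.559). NQO1, a quinone reductase, passed in the higher direction, but it was not well above background on any CONTROL array, so no size is given. TXN, thioredoxin, rose by 1.06 (SE 0.24), and TXNRD1, its reductase, fell by 0.80 (SE 0.19). Of 9 genes of xenobiotic metabolism, 3 rose and 2 fell (camera adjusted p = 0.680), among them AHR, the aryl hydrocarbon receptor, which fell by 1.12 (SE 0.14; −0.61 at a second lit probe), and TIPARP, a target of that receptor, which rose by 0.65 (SE 0.10).

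**Figure D3:**
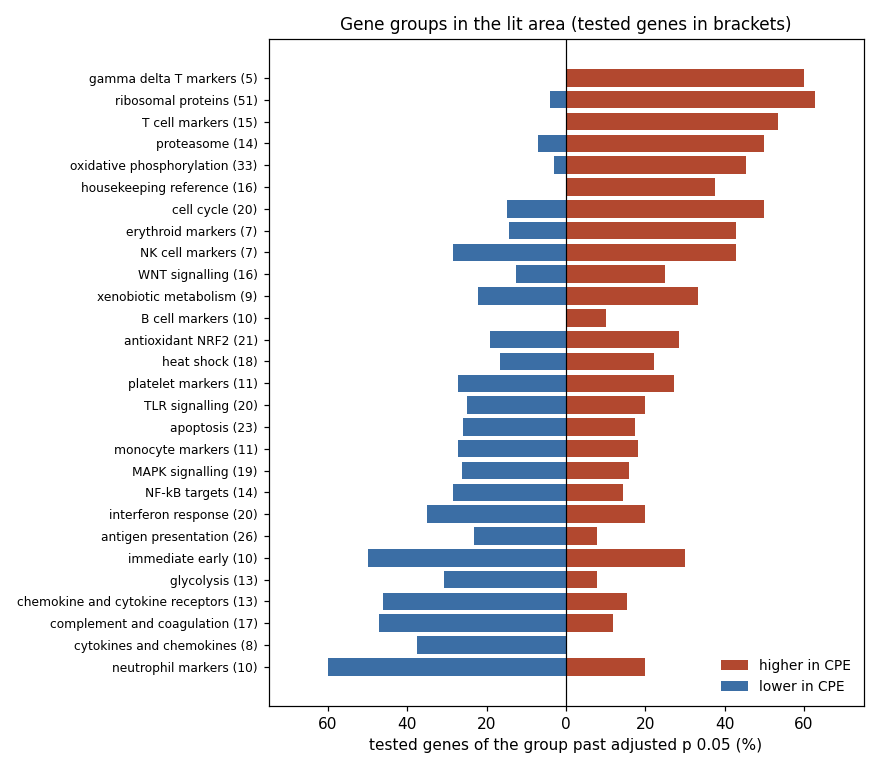
Percentage of tested genes of each gene list past an adjusted p of 0.05 in the lit area, higher in CPE to the right and lower to the left, with the number of tested genes in brackets. By camera, the ribosomal, T cell, oxidative phosphorylation and neutrophil lists passed, and none passed with an estimated correlation; taken relative to the median of all genes, the medians of the B cell, red cell, heat shock, platelet and NK cell lists changed sign under at least 1 scaling.

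Spike-in RNA, added in equal amounts, served as a measure of technical difference between the slides. The mean of the 10 spike-in probes over the whole array differed by 0.13 log2 units between CPE and CONTROL (0.05 ± 0.24 against −0.08 ± 0.19, SD, n = 4 each; exact two-sided permutation p = 0.457). The 7 spike-in probes above background in the lit area differed by 0.76 over the whole array (2.07 ± 0.35 against 1.31 ± 0.04, SD, n = 4 each; exact permutation p = 0.0286). Without scaling the 10-probe difference was 1.07 and with quantile normalisation 0.77, both with the smallest p that the exact permutation test can give, 0.0286. Measured at their lit spots, the same 7 probes differed by −0.083 (2.16 ± 0.05 against 2.24 ± 0.14, SD, n = 4 each; exact two-sided permutation p = 0.314), with single probes between −0.30 and 0.05. All 10 spike-in probes there differed by −0.20 (exact permutation p = 0.0286). Without scaling, the 7 probes at their lit spots differed by −0.26 (exact permutation p = 0.0857) and all 10 by −0.38 (exact permutation p = 0.0286).

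The authors' deposited table gives a mean log2 value per group and no spread, so no test can be made from it. For all 43653 probes, the difference of its CPE and Control columns was compared with that of the scanner values, with a slope of 1.00 and a median absolute difference of 0.0019. By those values, 5632 probes were at least 2-fold higher in CPE and 22831 at least 2-fold lower, with column medians of 0.46 for Control and −0.60 for CPE. FOS stood at 1.72 in its Control column and −2.03 in its CPE column, and RPLP2 at −3.24 and 3.43.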

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

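All tests of explanations and all splits of the arrays in this part were chosen after the results had been seen. Among 92 groups of 4 arrays tested, 10 had an array far from the other 3, all in named genes, where chance gives about 1 in 20.

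CPE array 2 read 5.34 for RPLP2 over the whole array, against 8.49 to 8.95 on the other CPE arrays. It also read 3.75 for POLR2K, against 6.73 to 7.31. CONTROL array 4 read 1.60 for HMGN2, against −0.67 to −0.32. In the lit area, CONTROL array 4 read 0.51 for MINDY3 against 1.21 to 1.25, −2.11 for ASS1 against −1.02 to −0.91, and −0.10 for ELMO1 against −0.31 to −0.29. CPE array 3 read 4.35 for MINDY3 against 3.14 to 3.32, and −5.05 for PNMA2 against −3.76 to −3.52. For ASB2, CONTROL array 1 read 0.79 against 0.39 to 0.45, and CPE array 4 read −2.35 against −2.21 to −2.19.

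The counts were set against all 35 splits of the 8 arrays into 4 and 4. For genes over the whole array, 1 split, the real one, gave as many as 2879, and the highest other gave 9. In the lit area, 1 split, again the real one, gave as many as 2539 genes, and the highest other gave 0. Every other split mixed the 2 groups and the 2 slides. Any difference between the groups then widened the spread within the split and lowered its count. The genes had also been chosen by a filter that used the real groups. These low counts are therefore no measure of chance and add nothing to the fits. The arrays of a group may also be technical replicates of 1 pool. A chance difference between the pools or the slides is therefore not excluded. For gene lists over the whole array, all 35 splits gave at least the real number of 0, and the highest other gave 2. For gene lists in the lit area, 4 splits gave at least the real number of 4, and the highest other gave 5, so chance cannot be excluded for the number of lists. The other splits with at least 4 lists each joined 3 CPE arrays with CONTROL array 4. The real split is also the split by slide, so none of these counts separates the extract from the slide.

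In the whole-array comparison, 908 genes rose at least 4-fold. A higher level of the transcripts themselves is argued against by their other probes. In the lit area, 40 of these genes had other probes well above background on all 8 arrays. Averaged per gene, those probes had a median log2 change of −0.062 (SE of the mean 0.086), against 3.16 at the whole-array probes of the same genes. Of these 908 genes, 0.110% had a spot lit on all 8 arrays, against 58.5% of all tested genes. Spots with little or no hybridisation signal on some arrays are therefore a candidate explanation. The share of 0.110% is weak support for it, because the whole-array scaling lowered the lit spots. Genes lit on all 8 arrays had a median log2 change of −1.07, so few of them could reach a 4-fold rise. Of the 908 rises, 202 lay at spots lit on the 4 CPE arrays but dark on some CONTROL array. The larger part, 705, lay at spots dark on some arrays of both groups, which does not by itself explain a rise in CPE. STRN3, CHRD and METTL2A, at spots lit on none of the arrays, were well above background on all 8, so a dark spot could still hold signal. For genes with no second lit probe, the level of the transcript was not measured in the lit area.

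In the lit area, the 5 immediate-early genes that fell, FOS among them, had a median log2 change of −1.79. Uneven signal left within the lit area is argued against as the whole cause, since after local centring their median was −1.59 and all 5 stayed past the threshold. A general difference of this size between the slides did not show in the 7 spike-in probes above background, where the largest difference was −0.30, or in the mean of all 10 (−0.20), but one that acts on some RNAs only could not be seen there. The extract and the slide, with the handling of its blood and RNA, cannot be told apart for these genes, because each slide held 1 group. An effect of the extract stays open and untested.

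Of 15 T cell markers in the lit area, 8 rose and none fell, and of 10 neutrophil markers 6 fell and 2 rose, with neither list past the threshold with an estimated correlation (adjusted p = 0.291 each). A lower share of neutrophils would raise the markers of all other cell types alike. The 15 T cell markers had a mean log2 change of 0.50 and 49 markers of 6 other cell types one of 0.08, a difference of 0.42 (permutation p = 0.0526). The 49 other markers had an SD of 0.78, against 0.417 between probes of the same gene, so they did not move alike. All genes tested in the lit area had an SD of 0.70, so this spread is not particular to these markers. Neither the permutation test nor the spread decides on a lower share of neutrophils. It stays open as the cause or as a part of it. A higher share of T cells is open, since the changes of the T cell markers had an SD of 0.438, about the 0.417 found between probes of the same gene. A change of transcription within the cells, from the extract or otherwise, was not tested, and slide and group cannot be told apart here either.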

How the results depend on the processing

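The lit-area values and their alternatives were chosen after seeing the data. The 20 named genes of the lit area kept their direction and their side of the threshold under every alternative that measured them, except PNMA2, which kept its direction and lost the threshold with normexp (−0.73). Over all genes named there by any rule, 2791 gene-by-setting values kept both, 211 kept the direction and lost the threshold, and 6 reversed. On the whole array the numbers were 464, 2 and 1. HMGN2 lost the threshold with normexp (2.94) and SSPO with the mean over probes (0.24). Unless stated, the cause of a change was not tested.

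On the whole array, 2879 genes passed. The count was 5689 with spike-in scaling, 1577 with normexp, 6817 with array weights (estimation not converged), and by construction lower with treat (1484) and an adjusted p under 0.01 (1225). Leaving out each array gave 1765 to 3608, with fewer arrays tested. The number of lists past camera, 0, became 1 without a filter, with the stricter filter and with the replicate block, 2 with the mean over probes, and 4 in the lit area. The replicate number was also the position on the slide in both groups. In the lit area r ran from −0.17 to 0.41 between same-numbered arrays and from −0.43 to 0.30 between the others. These overlapping ranges neither show a pairing by number nor exclude one. The difference of the 10 spike-in probes, 0.13, became 1.07 without scaling and 0.77 with quantile normalisation, and the 7 bright ones alone differed by 0.76. SSLP1 reversed to 0.90 with the mean over probes.

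In the lit area, 2539 genes passed. The count was 901 without scaling, 1166 with normexp and 3852 with local centring, and by construction lower with treat (525) and an adjusted p under 0.01 (1618). Leaving out each array gave 2065 to 2906. The number of lists, 4, was 2 with quantile normalisation and with the block, and 1 with scaling to bright probes, an adjusted p under 0.01, the larger neighbourhood and the wider area. It was 1 to 4 leaving out each array, 0 with an estimated correlation and 21 by fry, which asks another question. The spike-in difference of −0.083 became −0.20 with all 10 probes, and without scaling it was −0.26 for the 7 probes and −0.38 for all 10. Among named genes, 59 kept the direction and lost the threshold with treat, 41 with normexp and 39 without scaling. S100A12 reversed to −0.077 with quantile and −0.18 with normexp and quantile, GPX3 to 0.0082 with normexp, TRD@ to −0.037 with normexp and −0.14 with normexp and quantile, and PSMD1 to 0.26 with the mean over probes. Spots well above background were 57.5% to 69.3% of lit spots per array and 11.7% to 35.6% of the others, which limits what dim genes can show.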

Other observations

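The lists of cell cycle, proteasome, reference, glycolysis and heat shock genes did not pass camera in the lit area. Of 20 cell cycle genes, 10 rose and 3 fell (camera adjusted p = 0.180), against 1 and 1 without scaling and 5 and 1 with normexp, with the spindle checkpoint kinase gene BUB1 at 1.29 (SE 0.26), TOP2A at 1.06 (SE 0.29, groups overlapping) and RB1 at −0.64 (SE 0.09). A second lit probe gave −0.27 for BUB1 and 0.51 for TOP2A. Of 14 proteasome genes, 7 rose and 1 fell (adjusted p = 0.143), 8 and 1 adjusted over the list alone, with PSMA4 up by 1.04 (SE 0.08). Of 16 reference genes, 6 rose and none fell (adjusted p = 0.203), 2 of them the ribosomal protein genes RPLP0 (0.86, other lit probes −0.05 to 0.99) and RPS15A (0.51). Of 13 glycolysis genes, 1 rose and 4 fell (adjusted p = 0.367), with PFKFB3 at −1.31 (SE 0.25). Of 18 heat shock genes, 4 rose and 3 fell (adjusted p = 0.978), 3 and 3 adjusted over the list alone, HSF1 at 1.17 (SE 0.20) and HSPB8 at −0.62 (SE 0.09; −0.18 at a second lit probe). The median of this list relative to that of all genes changed sign with normexp. The direction with more genes past the threshold turned under at least 1 other scaling in the heat shock, apoptosis, MAP kinase, Toll-like receptor, WNT and NK cell lists.

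Defence and signalling genes moved both ways in the lit area. Of 20 interferon response genes, 4 rose and 7 fell (camera adjusted p = 0.426). The antiviral synthetase gene OAS2 passed in the lower direction but was not well above background on any CPE array, so no size is given. OAS1Z stood at −1.79 (SE 0.10) and IFITM1 at 1.39 (SE 0.36). Of 26 antigen presentation genes, 2 rose and 6 fell (adjusted p = 0.420), with the class II invariant chain gene CD74 at −0.93 (SE 0.08) and BOLA-DQA5 at 0.61 (SE 0.09). Of 20 Toll-like receptor pathway genes, 4 rose and 5 fell (adjusted p = 0.782), TLR3 at 1.25 (0.084 at a second lit probe) and TLR4 at −0.84. Of 14 NF-kB targets, 2 rose and 4 fell (adjusted p = 0.565), 3 and 6 adjusted over the list alone, with BCL3 at −1.59 (SE 0.14) and NOS2, the inducible nitric oxide synthase, at 1.07 (SE 0.25). Of 23 apoptosis genes, 4 rose and 6 fell (adjusted p = 0.559), BCL2L1 at 1.17 and FAS at −0.80, but 11 rose and 7 fell after local centring and 5 and 3 with spike-in scaling. Of 19 MAP kinase genes, 3 rose and 5 fell (adjusted p = 0.782), with DUSP4 at −1.80 (SE 0.21), but 9 rose and 3 fell after local centring and 4 and 4 with spike-in scaling. Of 16 WNT pathway genes, 4 rose and 2 fell (adjusted p = 0.838), 3 and 2 adjusted over the list alone, with FZD3 at 1.06 (SE 0.12). OAS1Z, BCL3 and DUSP4 were well above background on 2 of the 4 CPE arrays, and BCL2L1 on 1 of the 4 CONTROL arrays.

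Markers of the other blood cells gave no list past camera in the lit area. Signs of list medians under other scalings are given relative to the median of all genes. Of 10 B cell markers, 1 rose, JCHAIN at 1.27 (SE 0.11), and none fell (adjusted p = 0.420), and the relative median changed sign with local centring. Of 7 NK cell markers, 3 rose and 2 fell (adjusted p = 0.782), GNLY at 1.26 and NKG7 at −0.78, with another sign of the relative median under normexp and local centring. Of 11 monocyte markers, 2 rose and 3 fell (adjusted p = 0.949), MS4A7 at 0.83 and SIRPA at −0.84. Of 11 platelet markers, 3 rose and 3 fell (adjusted p = 0.838), PPBP at 1.47 and P2RY12 at −1.60, with another sign of the relative median under normexp. Of 7 red cell markers, 3 rose and 1 fell (adjusted p = 0.420), SELENBP1 at 1.00 and SLC25A37 at −0.56 (−0.034 at a second lit probe), with another sign of the relative median under quantile normalisation. Eosinophil and basophil markers and galectins had fewer than 5 genes in the lit area and were tested as lists over the whole array only, with 0 higher and 2 lower of 5 and 0 higher and 2 lower of 7 (adjusted p = 0.870 and 0.844). Their lit members included ALOX15 at −1.44 (SE 0.09), an arachidonate lipoxygenase of eosinophils, and LGALS3BP at −0.80 (SE 0.11) and LGALS1 at 0.40 (SE 0.14), whose groups overlapped.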
